A study of Mus musculus with 10 samples.

How the data were processed

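Bulk mRNA sequencing was done on smooth muscle cells from the aorta of mouse embryos at embryonic day 15.5. Per the labels and the series design text, mice heterozygous for Eln and carrying a green fluorescent Acta2 reporter were intercrossed, the embryonic aorta was digested with collagenase, and cells were sorted that were positive for the reporter, negative for CD31 (the endothelial surface protein encoded by Pecam1) and negative for DAPI, a dye that marks dead cells. RNA was made into libraries with a low-input mRNA kit, per the labels' protocols. There were 5 libraries from Eln+/+ and 5 from Eln-/- embryos. The allele that inactivates Eln, the number of embryos behind a library and whether replicates are separate embryos are not in the labels, so p-values measure only the spread between these libraries, which may be partly technical.

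The authors deposited 1 table with an estimated count per gene and library for 28165 genes, not scaled for library size. Its columns were matched to libraries by the sample names in the labels. Per the submitters' processing notes, STAR and DESeq2 were used with the genome build mm10. No version of either tool was given, and the program that made the counts, its annotation and its strand setting are not given in the sources used here. Between 23.5% and 48.8% of the values in a library were not whole numbers at a tolerance of 1e-06, so they were treated as estimated counts and rounded to whole numbers before any test. The table's gene spans were compared with GENCODE mouse release 21, which uses GRCm38, the assembly also called mm10. Chromosome, strand, start and end were the same for 27046 of the 28165 genes (96.0%). Since the strand setting is unknown, reads of genes whose exons overlap those of another gene cannot be assigned with certainty. Only some such genes are named as overlapping beside their values. Exons of Notch2, Notch3, Hoxc5, Ccn2, Col4a1 and Tagln, among others, overlap those of another gene as well.

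Genes were kept by edgeR's filterByExpr on the genotype, which left 15718. Libraries were scaled with TMM factors. The comparison of Eln-/- with Eln+/+ was made with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) with the genotype as the only term and Benjamini-Hochberg adjustment, at a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. CPM, counts scaled by library size, used the TMM factors, and log2 CPM values used a prior count of 2. A replicate is 1 library, and n = 5 in each genotype throughout. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

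There were 37 gene lists, 25 of cellular programs and 12 of markers of other cell types, and 585 of their 692 genes were tested. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the 37 lists, then with camera and an estimated correlation, and with fry, which asks whether the genes of a list move, on balance, one way. A score per library, the mean log2 CPM of a list, was compared by a two-sided exact permutation test over all 252 assignments of the libraries, whose smallest possible p is 0.00794. The lists, the test, part of the alternatives and the rule for named genes were fixed before the data were examined. That rule took Eln, the genes past the threshold with an average log2 CPM of at least 2 (there were none), up to 4 members of each program list by p, 13 further genes of smooth muscle and matrix biology, and the 2 most abundant members of each marker list. After the list results were seen, the members by p were limited to 4 for program lists past the threshold (2 higher, 2 lower) and to 1 for the others. Another 13 genes were chosen after their values were seen. Of these, 9 were not Eln or predicted gene models and had no overlap between genotypes, an average log2 CPM of at least 5 and an unadjusted p under 0.05, and the other 4 were among the genes tested and passed the threshold with another tool.

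Total counts ranged from 26951733 to 63866416 per library. The procedure was tested on counts simulated from the real gene means, library sizes and dispersions of this comparison, with 200 genes changed by known folds in each of 10 draws (a median of 14829 genes tested). At the observed spread between replicates, edgeR recovered 0 of 400 genes changed 2-fold, 5 of 400 changed 4-fold, 48 of 400 changed 8-fold, 119 of 400 changed 16-fold and 247 of 400 changed 64-fold. It called 8 of 146182 unchanged genes. A list of 20 genes shifted 4-fold was called by camera in 10 of 10 draws, and 1 of 360 unshifted lists was called. Simulated genes varied independently, whereas the fibroblast, Notch and immediate early lists had estimated correlations of 0.36, 0.25 and 0.77. The simulated list counts therefore do not measure false calls among correlated genes. With a biological coefficient of variation of 0.2 in place of the observed spread, 390 of 400 genes changed 2-fold were recovered.

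The alternatives fixed beforehand were RLE, upper quartile and library size scaling, no filter, a filter of 5 CPM in 5 libraries, DESeq2, limma-voom with and without sample quality weights, glmTreat against a fold of 1.2, the replicate number as a block, a covariate made from Y-linked genes, removal of haemoglobin genes, mitochondrial genes and Eln, leaving out each library in turn, and list scores from z-scores. Those chosen after seeing the data were a filter of 10 counts in every library, robust estimation, DESeq2 on the genes that pass filterByExpr, leaving out the 3 libraries with the fewest detected genes, and leaving out the 2 libraries with the highest immediate early genes. The last selects libraries by a measured value and is only a check of how much of a list value rests on them.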

Results

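Smooth muscle cells of the embryonic mouse aorta were profiled at embryonic day 15.5 to ask how loss of elastin, the core protein of elastic fibres encoded by Eln, alters their gene expression. There were 5 libraries of sorted Eln+/+ cells and 5 of sorted Eln-/- cells. Total estimated counts were 26951733, 63866416, 42937710, 52279252 and 39646351 in Eln+/+ replicates 1 to 5 and 56371507, 49802732, 40444163, 28367780 and 31366658 in Eln-/- replicates 1 to 5. At least 1 count was found for 15089 genes in Eln+/+ replicate 1, 15595 in Eln-/- replicate 4 and 15925 in Eln-/- replicate 5, against 18157 to 22951 in the other 7 libraries. The gene model CT010467.1, annotated as ribosomal RNA, took 5.53%, 5.99% and 5.52% of the counts in those 3 libraries and 0.225% to 2.96% in the others. The first principal component of log2 CPM held 50.8% of the variance and set the same 3 libraries, from both genotypes, apart from the rest. Across genes, the median correlation of log2 CPM between libraries was 0.768 within Eln+/+, 0.675 within Eln-/- and 0.735 between genotypes, and the highest of all, 0.939, joined Eln+/+ replicate 2 with Eln-/- replicate 1. Genes are not independent replicates.

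**Figure D1:**
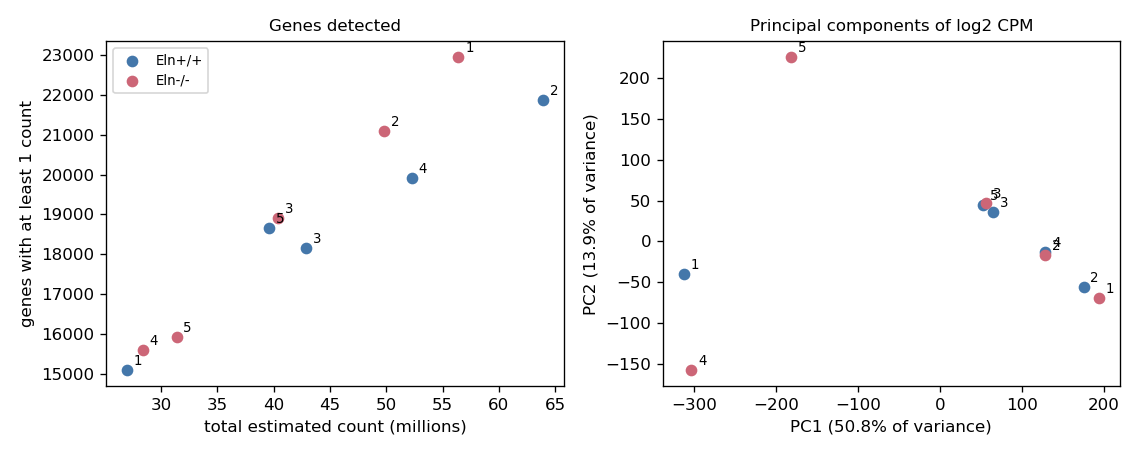
Left, genes with at least 1 count against the total estimated count; right, the first and second principal components of log2 CPM. Points are libraries coloured by genotype and numbered by replicate, and Eln+/+ replicate 1 and Eln-/- replicates 4 and 5 detect 15089 to 15925 genes and lie at negative values of the first component.

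Elastin is laid down by smooth muscle cells of the developing aorta, in layers that let the vessel wall recoil. Eln transcripts were nearly absent from every Eln-/- library. The gene lies on chromosome 5 from 134702593 to 134747323 on the minus strand (mm10), and its rounded counts were 36, 1, 0, 1 and 0 in Eln-/- replicates 1 to 5. In Eln+/+ replicates 1 to 5 they were 2409, 105866, 8603, 49878 and 31530. The mean was 608 ± 447 CPM in Eln+/+ and 0.116 ± 0.213 CPM in Eln-/- (SD, n = 5 each), with no overlap between genotypes and a log2 fold change of Eln of -12.19 (SE 1.64). Eln ranked 1 by p among the 15718 genes tested, yet its adjusted p in edgeR's quasi-likelihood test was 0.152 and missed the threshold of 0.05. It passed with DESeq2 (adjusted p = 1.30e-16), with limma-voom (adjusted p = 0.0155) and, with edgeR, without Eln-/- replicate 1 (adjusted p = 0.0110), and over all alternatives the adjusted p ranged from 1.26e-20 to 1.00. Gm30003, an antisense gene on the plus strand from 134747042 to 134822967 whose exons overlap the 5' end of Eln, had 11 to 232 counts in the Eln+/+ libraries and 4, 0, 0, 0 and 0 in Eln-/- replicates 1 to 5, and without known strand reads in that overlap cannot be assigned to either gene.

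**Figure D2:**
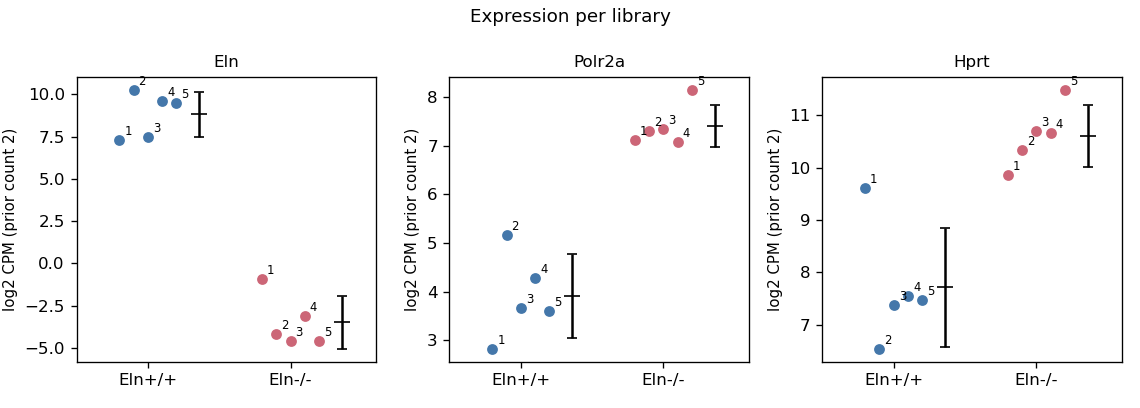
Log2 CPM (prior count 2) of Eln, Polr2a and Hprt in each library, with replicate numbers, and the mean and SD of 5 libraries per genotype as black bars. In none of the 3 genes do the genotypes overlap.

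No gene passed the threshold between genotypes with edgeR, 0 higher and 0 lower. At an unadjusted p under 0.05 there were 81 genes, 58 higher and 23 lower in Eln-/-, where uniform p-values would give 786. Other splits of the 10 libraries into 5 and 5 gave 26 to 4205 such genes with edgeR. The 786 therefore does not measure chance in these libraries. Other tools called a few genes each. DESeq2 without the filter called 21 higher and 7 lower. Most of these were genes that edgeR's filter had removed, such as Xirp1 and Fcgr3, which reached 10 counts in only 2 libraries each. DESeq2 on the edgeR-filtered genes called 4 and 2, limma-voom 1 and 1, and limma-voom with sample quality weights 5 and 2. In 48 genes, 22 higher and 26 lower, the libraries of the genotypes did not overlap, against 125 (0.794%) by chance. That 125 is an expected average over splits, which were uneven. At least 48 genes were found in 62 of all 126 splits, and the highest other split gave 2830, so 48 is not unusually few. The biological coefficient of variation was 1.16. At that spread 119 of 400 simulated 16-fold changes were recovered, so most changes of that size or smaller went undetected in the simulation. Simulated genes varied independently, and Eln missed the threshold in the real data at a log2 fold change of -12.19. The real limit of detection may therefore be higher.

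Among genes chosen after their values were seen, Polr2a and Hprt were abundant and higher in each Eln-/- library than in any Eln+/+ library, although neither passed the threshold with edgeR. Polr2a, the largest subunit of RNA polymerase II (chromosome 11, 69733997 to 69758637, minus strand), was at 17.5 ± 11.2 CPM in Eln+/+ and 176 ± 61.0 CPM in Eln-/- (SE 0.52, edgeR adjusted p = 0.331), and the log2 fold change of Polr2a was 3.33. Its adjusted p was 3.16e-07 with DESeq2 and 0.00276 with limma-voom and sample quality weights, and 1.82e-07 to 1.00 over all alternatives. Hprt, an enzyme of purine salvage (chromosome X, 52988137 to 53021659, plus strand), was at 282 ± 283 CPM in Eln+/+ and 1671 ± 724 CPM in Eln-/- (log2 fold change 2.57, SE 0.68, edgeR adjusted p = 1.00). Eln+/+ replicate 1 was at 784 CPM of Hprt, against 93.5 to 187 CPM in the other Eln+/+ libraries. Hprt passed only with limma-voom and sample quality weights (adjusted p = 0.00276) among the settings run, which reached 1.00. Tmem91 had 0 counts in all Eln+/+ libraries and 85, 65, 40, 30 and 125 in Eln-/- replicates 1 to 5 (edgeR adjusted p = 0.671). Pooled over libraries, that is 132-fold higher against a floor of 3 counts over the Eln+/+ group, which covers counting error only. Exons of Tmem91 overlap Exosc5 on the other strand. AA914427, an uncharacterised transcript on chromosome 16, had 1 count in Eln+/+ and 361 in Eln-/-, a ratio of 415 (95% exact interval 74.0 to 16434, counting error only). Gm47175 had 18 counts in Eln+/+ replicate 1, 0 in the other Eln+/+ libraries and 7 to 161 in Eln-/-, and passed only with limma-voom and sample quality weights.

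Ccn5, a matricellular protein of the CCN family, was at 29.5 ± 15.2 CPM in Eln+/+ and 221 ± 141 CPM in Eln-/- (log2 fold change 2.91, SE 0.62, edgeR adjusted p = 1.00) and passed with DESeq2 only. Tmem158 was at 35.7 ± 14.6 CPM and 107 ± 19.5 CPM (log2 fold change 1.59) and passed with DESeq2 on all genes only. Gja4, the gap junction protein connexin 37, and Arf6, a small GTPase of membrane traffic, had log2 fold changes of 1.73 and 1.56. Stimate was at 27.0 ± 4.27 CPM in Eln+/+ and 62.1 ± 34.5 CPM in Eln-/-. Fez1 was at 55.7 ± 17.1 CPM in Eln+/+ and 13.3 ± 7.48 CPM in Eln-/- (log2 fold change -2.06), and Adh1, an alcohol dehydrogenase, at 85.4 ± 43.7 and 23.7 ± 14.3 CPM (log2 fold change -1.85). Gja4, Arf6, Stimate, Fez1 and Adh1 passed in none of the settings run, and exons of Arf6 and Adh1 overlap those of Gm9887 and Gm16559.

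In the tests of gene lists, 3 of 37 passed with camera at a preset correlation. Fibroblast markers were lower in Eln-/-, with 8 of 11 measured members at negative fold changes and a median log2 fold change of -0.66 (camera adjusted p = 0.00102, and adjusted p = 0.998 with an estimated correlation). Dcn, the matrix proteoglycan decorin, was at 1566 ± 862 CPM in Eln+/+ and 647 ± 424 CPM in Eln-/-, and Lum, the related proteoglycan lumican, at 732 ± 423 and 371 ± 250 CPM. Dcn is also in the interstitial matrix list. Notch pathway genes were higher, with 14 of 16 members at positive fold changes and a median of 0.82 (camera adjusted p = 0.00114, and adjusted p = 0.998 with an estimated correlation). The Notch target Hes1 was at 70.5 ± 18.8 CPM in Eln+/+ and 136 ± 55.5 CPM in Eln-/- (log2 fold change 0.95, SE 0.40), and Nrarp, a target that feeds back on the pathway, at 6.99 ± 8.75 and 34.5 ± 13.9 CPM (log2 fold change 2.30, SE 1.26). Exons of Nrarp overlap Gm38287 on the other strand. Values for Rbpj, the DNA-binding partner of Notch, and for the receptor Notch2 were -0.92 and -0.20 on the log2 scale, and the latter was 0.24 without Eln+/+ replicate 2. Immediate early genes, which cells induce within minutes of stimulation or dissociation, were higher, with 23 of 24 members at positive fold changes and a median of 1.17 (camera adjusted p = 0.00472, and adjusted p = 0.998 with an estimated correlation). Klf2 was at 24.9 ± 26.9 CPM in Eln+/+ and 138 ± 232 CPM in Eln-/- (log2 fold change 2.48, and 0.48 without Eln-/- replicate 1), and the small heat shock protein Hspb1 at 41.2 ± 24.2 and 39.9 ± 27.6 CPM. The log2 fold change of Atf3, a stress-induced transcription factor, was 2.77 (SE 1.36). It rests on Eln-/- replicate 1, at 500 CPM against 1.32 to 26.9 CPM in the other 4 Eln-/- libraries, and was -0.48 without it.

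None of these 3 calls held with fry (adjusted p = 0.973 for each). No member of any list passed over all genes tested, and 0 passed adjusted over the list alone, where the smallest value in any list was 0.329. In exact permutation tests of the list scores the smallest unadjusted p was 0.0714, for glial markers, and each adjusted p was 1.00. Adjusted over 37 lists, 1 list alone at the smallest possible p of 0.00794 could not have passed. The fibroblast marker score was 4.03 in Eln+/+ replicate 1, 2.92 in Eln-/- replicate 4 and 3.24 in Eln-/- replicate 5, the 3 libraries with the fewest detected genes, and 5.80 to 7.26 in the others. Without those 3 libraries the fibroblast median was -0.42, the Notch median 0.99 and the immediate early median 1.67. Then 7 lists passed with camera, these 3 and contractile genes, inflammatory mediators, YAP/TAZ targets and oxidative phosphorylation genes, and none of the 7 passed with an estimated correlation (smallest adjusted p = 0.779). The immediate early score was 8.91 in Eln-/- replicate 1 and 7.18 in Eln+/+ replicate 2, against 3.31 to 5.89 in the others. Without Eln-/- replicate 1 the median log2 fold change of immediate early genes became -0.57 (camera adjusted p = 0.493) and the median log2 fold change of Notch pathway genes 0.21 (camera adjusted p = 0.0814), and without Eln+/+ replicate 1 the latter was 0.56 (camera adjusted p = 0.0683).

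**Figure D3:**
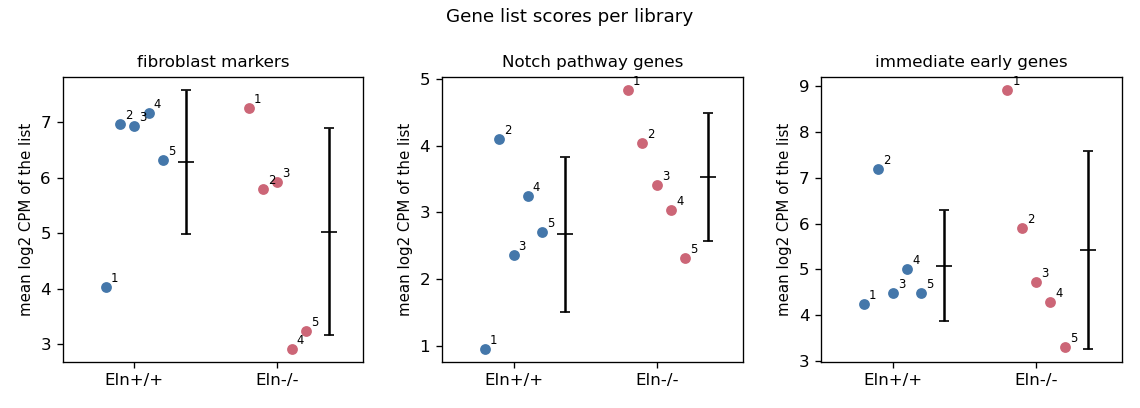
Mean log2 CPM of fibroblast markers, Notch pathway genes and immediate early genes in each library, numbered by replicate, with the mean and SD of 5 libraries per genotype as black bars. The genotypes overlap in each list, and Eln-/- replicate 1 has the highest immediate early score, 8.91.

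The smooth muscle and matrix programs did not pass in the reported edgeR fit. Contractile genes had a median log2 fold change of 0.24 (camera adjusted p = 0.514). Without the 3 libraries with the fewest detected genes their median was 0.58 (camera adjusted p = 3.00e-05, and adjusted p = 0.779 with an estimated correlation), and they passed in 3 of 28 alternatives. Without Eln-/- replicate 1 their median was -0.41 and with the replicate block -0.14, neither past the threshold. Acta2, whose promoter drives the reporter used to sort the cells, was at 942 ± 279 CPM in Eln+/+ and 1292 ± 504 CPM in Eln-/-, Tagln at 427 ± 213 and 751 ± 411, Myh11 at 10.5 ± 13.8 and 25.8 ± 52.2, and Cnn1 at 97.3 ± 57.9 and 172 ± 120. Csrp1, a LIM protein of muscle, had the smallest p of that list (log2 fold change 1.18, SE 0.46). Elastic fibre and microfibril genes other than Eln had a median of 0.15 and a camera adjusted p of 0.897. Lox, which cross-links elastin and collagen, was at 482 ± 336 CPM in Eln+/+ and 681 ± 754 CPM in Eln-/-. In the same order, the microfibril protein Fbn1 was at 103 ± 62.2 and 100 ± 161, Fbln5 at 1469 ± 861 and 1977 ± 1953, and Ltbp1 at 60.1 ± 61.2 and 158 ± 218. The median log2 fold change of interstitial matrix genes was 0.12 (camera adjusted p = 0.166). The direction of the camera test was already down in the reported fit, against the sign of that median. Interstitial matrix genes passed in 8 of 28 alternatives. Among these were the replicate block (-1.13) and sample quality weights (-0.87), with all libraries and the sign of the median turned. In neither did they pass with an estimated correlation. Col1a1, a chain of type I collagen, was at 2318 ± 1990 and 2570 ± 4048 CPM. Without Eln-/- replicate 1 the medians of interstitial matrix, elastic fibre and basement membrane genes were -1.54, -0.71 and -1.28, all past the threshold with camera and none with an estimated correlation. Without that library the log2 fold changes of Myh11, Lox, Fbn1, Fbln5 and Col1a1 were -2.11, -0.34, -1.85, -0.30 and -1.56, and the log2 fold change of Ltbp1 went from 1.39 to 0.070. With all libraries basement membrane genes had a median of 0.93 (camera adjusted p = 0.922). Col4a1, a chain of type IV collagen, had a log2 fold change of 1.68 (SE 1.05) that turned to -0.83 without Eln-/- replicate 1. Integrin and focal adhesion genes had a median of 0.15 (camera adjusted p = 0.940), and matrix protease and inhibitor genes a median of -0.11 (0.825). Itgb3, an integrin subunit, was at 17.9 ± 17.5 and 14.3 ± 16.5 CPM, Tln1, which links integrins to actin, at 23.9 ± 19.0 and 46.3 ± 36.7, and Mmp19 at 2.14 ± 2.36 and 0.468 ± 0.704.

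Cell cycle genes did not pass either. S phase and G2/M genes had medians of -0.09 and 0.05 (camera adjusted p = 0.988 and 0.995). Rrm1, a ribonucleotide reductase subunit, was at 194 ± 105 CPM in Eln+/+ and 111 ± 90.5 CPM in Eln-/-, the mitotic kinase Cdk1 at 142 ± 60.2 and 237 ± 136, and the proliferation marker Mki67 at 4.10 ± 5.78 and 12.6 ± 23.7. The log2 fold change of Mki67 was 1.62, and -0.99 without Eln-/- replicate 1. Among signalling lists, TGF-beta and BMP genes had a median of 0.08 (camera adjusted p = 0.514), YAP/TAZ targets 0.49 (0.203, and 1.00 with an adjusted p of 0.00437 without the 3 libraries with the fewest detected genes, where the adjusted p = 0.784 with an estimated correlation, and -0.53 without Eln-/- replicate 1), growth factor signalling genes 0.18 (0.782) and vasoactive receptors and channels -0.13 (0.387). Ccn2, in the first 2 of these lists, was at 30.4 ± 22.6 CPM in Eln+/+ and 78.5 ± 71.1 CPM in Eln-/-. The log2 fold change of Ccn2 was 1.37, and 0.65 without Eln-/- replicate 1. Igfbp2, a binding protein of insulin-like growth factors, had the smallest p of the growth factor list (log2 fold change 1.27, SE 0.46). Rgs5, a regulator of G protein signalling, was at 692 ± 351 and 1302 ± 800 CPM, and Notch3 at 9.85 ± 6.04 and 17.4 ± 12.8. Notch3 was at 40.4 CPM in Eln-/- replicate 1 and at 10.6 to 12.3 CPM in the other Eln-/- libraries. The Notch ligand Jag1 was at 54.3 ± 30.4 and 95.3 ± 103 CPM (log2 fold change 0.81, and -0.096 without Eln-/- replicate 1). Histone acetylation enzymes had a median of 0.30 (camera adjusted p = 0.897), with the acetyltransferase Ep300 at 1.84 ± 1.04 and 3.11 ± 1.31 CPM and the deacetylase Hdac2 at 33.5 ± 14.1 and 55.0 ± 15.6.

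Stress and metabolic lists had small medians apart from inflammatory mediators, at 0.90 (camera adjusted p = 0.0746), where Ptgs2, which makes prostaglandins, was at 0.854 ± 1.04 CPM in Eln+/+ and 17.5 ± 38.3 CPM in Eln-/-. The median of inflammatory mediators was 1.81 without the 3 libraries with the fewest detected genes (camera adjusted p = 0.00107, and adjusted p = 0.779 with an estimated correlation) and 0.29 without Eln+/+ replicate 2 and Eln-/- replicate 1 (camera adjusted p = 0.762), and the list passed in 10 of 28 alternatives. The medians were 0.31 for oxidative phosphorylation genes (camera adjusted p = 0.387, and -0.16 with an adjusted p of 0.00101 without the 3 libraries, where the adjusted p = 0.807 with an estimated correlation), -0.08 for glycolysis genes (0.922), -0.02 for hypoxia response genes (0.897), -0.06 for cholesterol synthesis genes (0.922), 0.17 for unfolded protein response genes (0.514), 0.20 for p53 targets (0.514) and -0.01 for interferon response genes (0.825). The members with the smallest p in these lists were Uqcrc2, Ldha, Bhlhe40, Hsd17b7, Sdf2l1, Ei24 and Ifit3, with log2 fold changes of -0.33, 0.51, 1.59, 0.70, 0.84, 1.07 and 2.07. Without Eln-/- replicate 1 the log2 fold change of Bhlhe40 was -0.096 and the log2 fold change of Ptgs2 -1.13. Hox genes, which mark position along the body axis, had a median of -0.37 (camera adjusted p = 0.982), with Hoxc5 at 11.9 ± 6.63 and 3.57 ± 4.01 CPM, and chondrogenic and osteogenic genes a median of -0.52 (0.988), with the cartilage regulator Sox9 at 46.2 ± 46.1 and 25.6 ± 19.8 CPM. The log2 fold change of Sox9 was -0.85, and -0.079 without Eln+/+ replicate 2.

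Markers of other cell types, apart from fibroblast markers, did not pass with camera in the reported edgeR fit. Haemoglobin transcripts of red cells, Hbb-bs at 2251 ± 4321 CPM in Eln+/+ and 772 ± 1229 CPM in Eln-/- and Hba-a2 at 1102 ± 1780 and 341 ± 349, belonged to a list with a median of -1.54 (camera adjusted p = 0.138). Without Eln+/+ replicate 1, at 9977 CPM of Hbb-bs and 4276 CPM of Hba-a2, the log2 fold changes turned to 1.31 and 0.17 and the median log2 fold change of erythroid markers to 0.24 (camera adjusted p = 0.919). That list passed in 10 of 28 alternatives (smallest camera adjusted p = 0.000788, with a median of -2.52 without Eln-/- replicate 4), mesothelial markers passed in 3, and neither passed with an estimated correlation in the settings where it was run. Medians were -0.96 for mesothelial markers (camera adjusted p = 0.138), 0.82 for epithelial markers (0.166) and -0.52 for glial markers (0.387). They were -0.25 for neuronal markers (0.782), -0.49 for cardiomyocyte markers (0.859), -0.27 for macrophage and leukocyte markers (0.897) and 0.12 for skeletal muscle markers (0.897). Pericyte markers had a median of -0.15 (0.928) and airway and visceral smooth muscle markers -0.09 (0.940). Endothelial markers had a median of 0.43 (0.922). It was -1.81 with an adjusted p of 0.0293 with DESeq2 run without the filter, so that its members were not held to the same filter. Only 2 epithelial, 3 glial, 3 macrophage and 4 endothelial markers were measured in the reported edgeR fit. Neuronal and airway and visceral smooth muscle markers also had 4 each, and mesothelial, cardiomyocyte and pericyte markers 5 each. The atrial myosin light chain Myl7 was at 165 ± 211 and 166 ± 206 CPM, the endothelial gene Egfl7 at 16.9 ± 6.97 and 24.8 ± 17.5, the pericyte gene Kcnj8 at 152 ± 73.7 and 123 ± 80.7, the mesothelial gene Upk3b at 39.9 ± 44.7 and 20.5 ± 25.8 (log2 fold change -0.96, and -0.026 without Eln+/+ replicate 2), and the neuronal gene Stmn2 at 13.6 ± 7.34 and 3.99 ± 2.77. The direction of the camera test differed from the sign of the median in 13 lists, namely interstitial matrix, growth factor, interferon, hypoxia, elastic fibre, glycolysis, integrin, Hox, G2/M, cardiomyocyte, macrophage, pericyte, and airway smooth muscle genes. It differed from the sign of the mean in 9 lists, which were interstitial matrix, growth factor, elastic fibre, integrin, Hox, G2/M, cardiomyocyte, pericyte and skeletal muscle genes.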

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

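The tests of Hprt, Polr2a and immediate early genes without the 3 libraries with the fewest detected genes, and of sequence carried by the allele, were chosen only after the results were seen. Single libraries lay far from the other 4 of their genotype in 26 of 239 sets of values compared, by the ratio of the gap to the range against a critical value of 0.71. Chance gives about 1 in 20 for independent, normally distributed values. The sets share the same libraries, so the 26 cannot be set against that rate. For AA914427, Gm30003 and Gm47175 the other 4 libraries all had 0 counts, which fixes the ratio at 1. Eln+/+ replicate 1 was low in several of the 26 sets. Its log2 CPM was 3.34 for Rbpj, -4.60 for Hsd17b7, 3.88 for Rrm1, 4.96 for Lox, 5.68 for Lum and 0.047 for Stmn2. Its list scores were also low, at 3.31 for cholesterol synthesis genes, 4.03 for fibroblast markers, -0.062 for Hox genes, 1.02 for hypoxia response genes, 3.93 for unfolded protein response genes and 2.43 for vasoactive receptors and channels. The same library was high for AA914427 (-3.22) and Gm47175 (0.30), where the other Eln+/+ libraries had 0 counts. Eln-/- replicate 1 was high for Klf2 (9.11), Mmp19 (0.82), Col4a1 (7.24), Notch3 (5.34), Gm30003 (-3.38) and the inflammatory mediator score (6.77). Eln-/- replicate 4 was low for Stmn2 (-3.14) and for Kcnj8 (-1.59, where the other 4 lay between 6.56 and 7.67). Polr2a was highest in Eln-/- replicate 5 (8.15), Fez1 lowest of Eln+/+ in replicate 2 (4.78), Acta2 lowest of Eln+/+ in replicate 3 (8.88), and the immediate early score highest of Eln+/+ in replicate 2 (7.18).

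Eln+/+ replicate 1 and Eln-/- replicates 4 and 5 stood apart from the other 7 libraries in detected genes and on the first principal component. Depth alone is argued against, since at an equal total of 26951681 counts the highest of the 3 still detected 15721 genes and the lowest of the other 7 detected 17510. The same was found without the ribosomal RNA gene and mitochondrial genes, at 15721 against 17453. For cells of another type, 0 of 12 marker lists had a summed CPM higher in each of the 3 than in each of the other 7, although erythroid markers reached 18904 CPM in Eln+/+ replicate 1 and 5155 CPM in Eln-/- replicate 4. Fewer sorted cells or less RNA at the start may still be the source, which no value here decides. Beyond cells of another type no biological explanation was tested, since the 3 libraries come from both genotypes.

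Immediate early genes were higher in Eln-/- with camera at a preset correlation, a median log2 fold change of 1.17. The 3 libraries with few detected genes are argued against as the source, since without them the median was 1.67 (camera adjusted p = 3.4e-08, and 0.779 with an estimated correlation). Without Eln+/+ replicate 2 and Eln-/- replicate 1, which had the highest scores, it was 0.41 (bootstrap SE 0.19, camera adjusted p = 0.183), between the bounds set for that explanation. That SE resampled genes, not libraries, and leaves out the spread between libraries. Without Eln-/- replicate 1 alone the median turned to -0.57. Whether cells of that library were stimulated more during dissociation, or the genotype raises these genes, cannot be told apart with 1 such library per genotype.

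Hprt and Polr2a, on chromosomes X and 11, were both higher in each Eln-/- library. The 20 nearest measured genes had a median log2 fold change of 0.055 (bootstrap SE 0.14) and a highest of 0.67. This argues against a change of their surroundings in the genome. For 27 other RNA polymerase II and purine synthesis genes the median was 0.13 (bootstrap SE 0.10) and the highest 0.85. This argues against a change of their pathways. Both bootstraps resampled genes, not libraries. Their SEs leave out the spread between libraries, and the uncertainty of the medians may be larger. Without the 3 libraries with few detected genes the smaller of the 2 fold changes was 2.95 (SE 0.43). A candidate explanation is that the inactivated Eln allele carries sequence of both genes, as selection cassettes can, so that reads from it are counted at both. The ratio of Hprt to Polr2a was 6.61 to 11.9 in the Eln-/- libraries. In Eln+/+ it was 111 in replicate 1, a library with few detected genes, and 2.60 to 14.6 in the others. The SD of the log2 ratio in Eln-/-, 0.33, lay at percentile 6.41 of random gene pairs of like level (median 1.29). That fell short of the bound of 5 set for the test. Carried sequence and a true rise of both genes therefore cannot be told apart without reads or the allele's structure.

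The number of genes called was set against other splits of the 10 libraries into 5 and 5. With edgeR the genotypes gave 0 genes, so that 100 of 100 splits had to give at least as many and the comparison says nothing about chance; the highest other split gave 1266. With sample quality weights, 13 of 100 splits gave at least the 7 genes of the genotypes, with a highest other of 102, and 62 of all 126 splits gave at least as many genes without overlap, 48 for the genotypes and 2830 for the highest other. Chance is not excluded for the count with sample quality weights or for the count without overlap. The split with 1266 genes set Eln+/+ replicates 1 and 5 and Eln-/- replicates 3, 4 and 5 against the rest. This points to a structure of the libraries that is not the genotype. Those 5 libraries had the lowest total counts, 26951733 to 40444163, against 42937710 to 63866416 in the rest. The share of the ribosomal RNA gene was also higher in each of them than in any of the rest. Whether either difference underlies the split was not tested.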

How the results depend on the processing

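DESeq2 on filterByExpr genes, robust estimation, the filter of 10 counts in every library and the settings that leave out 2 or 3 libraries together were chosen after seeing the data. Genes higher and lower were 21 and 7 with DESeq2, 4 and 2 with DESeq2 on filterByExpr genes, 1 and 1 with limma-voom, 5 and 2 with sample quality weights, and 0 and 1 without the 2 libraries with the highest immediate early genes, and 0 and 0 in the other settings that used all libraries or left out 3. Leaving out 1 library gave 0 higher and 0 to 1 lower. The log2 fold change of Eln passed with DESeq2 (-12.24, also on filterByExpr genes), limma-voom (-13.22), sample quality weights (-14.63) and without those 2 libraries (-14.69), and was -15.14 to -11.77 with 1 library left out. The adjusted p for the log2 fold change of Eln spanned 1.26e-20 to 1.00 over its 26 alternatives. Polr2a stayed between 2.95 and 3.84, Hprt between 2.29 and 3.44, and both were positive in all 27.

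Lists past the threshold, 3 in the reported test, were 0 with an estimated correlation and 0 with fry (medians of the 3 lists as reported, -0.66, 0.82 and 1.17), 5 with library size only, 7 with either DESeq2 fit, 5 with sample quality weights, 7 without the 3 libraries with the fewest detected genes, and 3 to 10 with 1 library left out, with 10 without Eln-/- replicate 4 and 8 without Eln-/- replicate 1. With an estimated correlation 0 lists passed in any setting where it was run. The Notch call was lost with DESeq2 (0.62), 10 counts in every library (0.56), without Eln+/+ replicate 1 (0.56) and without Eln-/- replicate 1 (0.21, the lowest of a range up to 1.04). Of lists not past the threshold in the reported test, inflammatory mediators and erythroid markers each passed in 10 of 28 alternatives, with medians of 0.063 to 1.81 and -2.52 to 0.24 over all of them, interstitial matrix genes in 8, oxidative phosphorylation genes in 6, YAP/TAZ targets in 4, contractile genes and mesothelial markers in 3 each, and basement membrane genes in 2. Others passed in at most 1. The immediate early call was lost with the replicate block (0.29), the sex covariate (1.05), without the 2 libraries (0.41) and without Eln-/- replicate 1 (-0.57, the lowest of a range up to 2.31 over single libraries left out). The fibroblast call was kept in all settings but the estimated correlation and fry, at -1.47 to -0.52 with 1 library left out. The sign changes given next are those of medians. In the reported test the direction of camera was already down for interstitial matrix, growth factor and elastic fibre genes. Medians that changed sign and passed with DESeq2 run without the filter were those of interferon response genes (0.34) and endothelial markers (-1.81). The median of oxidative phosphorylation genes did so without the 3 libraries (-0.16). The median log2 fold change of interstitial matrix genes did so with sample quality weights (-0.87), the replicate block (-1.13), the sex covariate (-0.00538) and without the 2 libraries (-1.05). Over single libraries left out, sign changes past the threshold occurred without Eln-/- replicate 1 for growth factor (-0.68 to 0.58), elastic fibre (-0.71 to 0.74) and basement membrane genes (-1.28 to 1.63), without Eln-/- replicate 4 for oxidative phosphorylation genes (-0.42 to 1.01), and without Eln-/- replicate 1, Eln+/+ replicate 1 or Eln+/+ replicate 5 for interstitial matrix genes (-1.54 to 0.66). Apart from these, 270 of 3127 alternative values of genes, lists and scores changed sign with neither value past the threshold, and 29 of 78 genes and 32 of 37 lists changed sign in at least 1 setting. The cause was not tested.

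Pairing by replicate number was not seen, but it is not excluded, and the labels do not state it. The correlation of same-numbered libraries' deviations from their group means was -0.56 to 0.51, and over 0.1 in 2 of 5 pairs. Only 1 of 5 correlated best with its own number. These deviations also hold the difference that sets the libraries with the fewest detected genes apart, which could hide a pairing. With the replicate block 0 genes were higher and 0 lower, the immediate early median was 0.29 (camera adjusted p = 0.232) and the median log2 fold change of interstitial matrix genes -1.13 (0.00447). Totals were at least 26951733 counts per library, and with simulated counts of the same totals 0 of 400 genes changed 2-fold were recovered at the observed spread and 390 of 400 at a coefficient of variation of 0.2.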

Other observations

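Transcripts that mark the sex of an embryo differed between libraries. Xist, the RNA that silences an X chromosome in female cells, was at 25.0 and 54.1 CPM in Eln+/+ replicates 3 and 5 and at 0 counts in Eln+/+ replicates 1, 2 and 4. The Y-linked gene Ddx3y was at 91.3 and 80.0 CPM in Eln+/+ replicates 2 and 4, at 10.4 CPM in replicate 1, at 0.020 CPM in replicate 3 and at 4.63 CPM in replicate 5. Both were counted in each Eln-/- library. Xist was at 11.7, 14.0, 2.64, 0.363 and 7.24 CPM and Ddx3y at 30.1, 21.8, 24.6, 4.65 and 10.8 CPM in Eln-/- replicates 1 to 5. The Y-linked gene Uty was at 29.7 and 29.9 CPM in Eln+/+ replicates 2 and 4, at 0 counts in Eln+/+ replicates 3 and 5, and at 2.45 to 18.7 CPM in the Eln-/- libraries. How many embryos went into a library is not in the labels. Xist beside Y-linked RNA argues against a single embryo behind each of Eln-/- replicates 1, 2, 3 and 5, unless material was mixed between libraries. Xist was too low in Eln-/- replicate 4 to say. Eln+/+ replicates 2 and 4 had Y-linked RNA without Xist, and Eln+/+ replicate 3 had Xist with almost no Ddx3y. What a replicate holds may therefore differ between genotypes. The mix of sexes may also differ between genotypes, and its effect cannot be told apart from that of Eln. With the covariate made from Y-linked genes 0 genes were higher and 0 lower. The reported fit without it gave the same counts, so they do not show whether sex matters. With that covariate the immediate early call was lost and the interstitial matrix median changed sign.

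Several gene groups differed between libraries of the same genotype. The score of nuclear-encoded oxidative phosphorylation genes was 9.49 in Eln+/+ replicate 1, 9.69 in Eln-/- replicate 4 and 8.84 in Eln-/- replicate 5, against 6.63 to 8.14 in the other libraries. The contractile score was 6.09 in Eln+/+ replicate 2 and 6.31 in Eln-/- replicate 1, the highest of the 10, and 2.96 in Eln-/- replicate 5, the lowest. Cardiomyocyte markers summed to 535, 481, 523 and 382 CPM in Eln+/+ replicates 1 and 2 and Eln-/- replicates 2 and 4, and to 1.18 to 48.2 CPM in the other 6 libraries.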
